A study of Homo sapiens with 2 samples.

How the data were processed

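Transcripts of single MCF10A cells were counted by droplet single-cell RNA sequencing in 2 pooled libraries, 1 per biological replicate. Per the labels, cells of each condition were marked with sample tags of the BD Single-Cell Multiplexing Kit (Human), pooled, fixed in methanol and stored frozen before sequencing. The names and doses of the MEK and PI3K inhibitors are not given in the sources used here. The deposited values are raw UMI counts per gene symbol and cell, with no normalisation by the authors, which whole numbers from 0 in both tables bear out. The authors name Cell Ranger 3.0.2, Seurat (its version is not given in the sources used here) and genome build GRCh38. The rule for tag calls, the annotation release, the strand setting and the cell filter are not given in the sources used here. Every deposited cell had a single tag, between 1502 and 4496 detected genes and at most 10.0% mitochondrial-encoded UMIs. Positions come from a copy of GENCODE v29 on GRCh38, whose release may differ from the one the authors counted with.

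The tag tables list 8641 barcodes for library 1, of which 4848 (56.1%) were called doublets, 616 negative and 3177 single-tagged, and 6161 for library 2, of which 2478 (40.2%) were called doublets, 262 negative and 3421 single-tagged. Count tables held 2616 and 2221 of the single-tagged cells. Doublets of cells with the same tag cannot be seen by tags, and the tag shares put them at 23.6% and 13.9% of single-tagged barcodes. Depth per cell ran from 3726 to 30865 UMIs in library 1 and from 3141 to 31090 in library 2. A filter at 1000 UMIs and 20% mitochondrial-encoded UMIs removed 0 cells. The tables list 17830 and 16740 genes, and the 16387 in both were used. Conditions were taken from the tag annotation. In libraries 1 and 2 there were 175 and 29 unstimulated cells and 488 and 64 cells at 15 h. At 20 h there were 438 and 233 cells with EGF alone, 216 and 244 with the MEK inhibitor and 332 and 187 with the PI3K inhibitor, and at 30 h 245 and 344, 346 and 616, and 376 and 504. No condition combined both inhibitors, so the comparison with such cells that had been foreseen was not made.

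Counts were summed per library and condition, and the 16 sums were fitted with edgeR 4.0.16 (quasi-likelihood F test, filterByExpr, TMM scaling) on R 4.3.3 with limma 3.58.1. The fit held a term for the library as a block, and adjusted p is Benjamini-Hochberg over 11147 tested genes with a threshold of 0.05. It had 7 residual degrees of freedom, a biological coefficient of variation of 0.060 and prior degrees of freedom of 43.3; log2 differences per library used a prior count of 2. The block was checked on 4706 genes with at least 20 CPM. The deviations of conditions from their means correlated between conditions of the same library with a median r of 0.588 over 28 pairs of conditions (0.281 to 0.677). Profiles of the libraries correlated across genes with r = 0.906 in unstimulated cells and 0.964 to 0.985 in the other conditions. With 2 sums per condition no regrouping of samples can test a comparison. Counts were first simulated for the MEK inhibitor against EGF alone at 30 h on 10502 genes. There 32.3%, 75.4% and 98.4% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered. Of 10312 unchanged genes 11 were called, and a comparison without changes gave 0 calls. Since most genes were left unchanged, this does not test the scaling where many genes change, as 4216 of 11147 did in the data.

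Of 23 gene lists, 22 with at least 3 measured genes were tested with camera at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry, which asks whether genes move one way on balance. A list is called by camera at the preset correlation unless fry is named, and adjusted p is over the lists of a comparison. They are MEK/ERK output genes, ERK-induced feedback and AP-1 genes, EGFR ligands, FOXO targets and PI3K feedback, sterol biosynthesis and uptake, fatty acid synthesis, glycolysis, ribosome biogenesis and MYC targets, the ATF4 amino acid response, lysosome and autophagy, G1 cyclins and CDK inhibitors, S phase, G2/M, p53 targets, interferon response, squamous differentiation and keratinocyte stress, basal, luminal, mesenchymal and matrix, YAP/TEAD targets, heat shock, mitochondrial-encoded transcripts, and markers of other cell types, which were only counted. Of 450 list genes 20 were not matched in both tables and 7 were matched by an older symbol. In a simulated PI3K comparison at 30 h with the S phase list raised by 0.7, 0 other lists were called. Genes were drawn independently there, so this does not test the preset correlation on genes that move together.

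The genes to be named were set by a rule. For each inhibitor against EGF alone these were the 6 largest rises and 6 largest falls with adjusted p under 0.05, the same sign in both libraries and a mean of at least 20 CPM in either condition. Other comparisons gave the largest 4 each way. Each list added up to 4 members with the smallest adjusted p, and 10 direct targets and pathway members were added as a group, 1 of which is not reported here. The lists, the named-gene rule, the fit, the comparisons and most alternatives were set before the data were examined. Alternatives set later were sums over S and G2/M cells, a fit without the unstimulated and 15 h cells, an upper limit of 4000 detected genes, list calls with library totals only, and the correlation of inhibitor changes taken from different libraries.

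Phases were called with scanpy 1.11.5 (Python 3.11.15) per library from 43 S phase and 54 G2/M genes, on counts thinned to 6500 UMIs per cell. The 449 cells below that depth got no call, 4388 were called and 2082 of these were called G1. No test was made across cells. The fit was repeated on sums over G1-called cells (8491 genes) and over S and G2/M cells. The overlap of the inhibitors was set beside 100 simulated draws of unchanged conditions. Alternatives were DESeq2 1.42.0, RLE size factors, library totals only, other low-count and cell filters, no replicate block, only the conditions compared, no cells among the top 5% by UMIs, 29 cells in every sum, thinned cells, a minimum log2 change of 0.5, each replicate left out, unthinned phase calls and calls from list shares above the median plus 2 median absolute deviations. Scaling by library totals moved the median log2 change of all genes by more than 0.1 with the PI3K inhibitor at 20 h (by -0.143), with the MEK and PI3K inhibitors at 30 h (-0.177 and -0.235), at 15 h of EGF (0.191), between the times with the MEK inhibitor (-0.105) and in the difference of MEK changes between times (-0.123).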

Results

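MCF10A is an immortalised, non-tumorigenic human breast epithelial line that depends on EGF to proliferate. Its cells were given EGF, an inhibitor of MEK (the kinase that activates ERK) or of PI3K (the lipid kinase upstream of AKT) was added to some cultures at 15 h, and transcripts of single cells were counted at 20 h and 30 h. Cells without EGF (0 h) and cells at 15 h of EGF alone were measured beside them, which makes 8 conditions. All conditions of a biological replicate carried their own sample tags and were pooled, so each of the 2 replicates is 1 library and n = 2 for every condition. The tables held 2616 cells with 33089090 UMIs for library 1 and 2221 cells with 28542571 UMIs for library 2, with median depths of 12259 and 12332 UMIs per cell. The summed counts of a condition ran from 213208 UMIs (29 unstimulated cells of library 2) to 8508781 UMIs (616 cells with the MEK inhibitor at 30 h in library 2). The comparisons ask what each inhibitor did to expression and to cell cycle phase once EGF had already acted.

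Cells given EGF alone moved from G1 calls at 0 h to S calls at 20 h and G2/M calls at 30 h. The share called G1 was 80.9% ± 22.9 at 0 h (SD, n = 2), 51.2% ± 14.0 at 15 h, 23.9% ± 7.89 at 20 h and 13.2% ± 7.34 at 30 h. With EGF alone 69.7% ± 6.71 of cells were called S at 20 h and 63.1% ± 13.1 were called G2/M at 30 h. With the PI3K inhibitor the G1 share was 57.5% ± 9.18 at 20 h and 77.5% ± 7.41 at 30 h, and at 30 h it exceeded that of EGF alone by 64.4 and 64.3 percentage points in libraries 1 and 2. With the MEK inhibitor at 20 h 60.6% ± 3.95 of cells were called S, which was 7.19 and 11.1 points below EGF alone in libraries 1 and 2, and the G1 share lay 6.93 and 7.53 points above it. At 30 h only 3.45% ± 0.902 of MEK-inhibited cells were called S, against 23.7% ± 5.73 with EGF alone, while 47.9% ± 22.8 were called G2/M. The S share with the MEK inhibitor lay below that of EGF alone by 23.7 points in library 1 and 16.9 points in library 2. The G2/M share with the MEK inhibitor at 30 h was 31.8% in library 1 and 64% in library 2, so its mean rests on libraries that differ. With the PI3K inhibitor 12.5% ± 4.27 were called G2/M at 30 h. An exact two-sided permutation test of 2 libraries against 2 cannot give a p below 0.333, so no phase difference was tested. Calls were made at 6500 UMIs per cell, and 33.6% of called cells lay within 0.05 score units of a phase boundary. Without thinning the S share with the MEK inhibitor at 30 h was 3.18% and 1.46% in libraries 1 and 2, the G1 share with the PI3K inhibitor at 30 h was 82.4% and 71.2%, and the G2/M share with EGF alone at 20 h was 6.39% and 14.2%. With calls from list shares the G1 share with EGF alone was 41.4% and 41.8% at 20 h and 25.6% and 32.3% at 30 h, and with the PI3K inhibitor 86.5% and 96.0% at 30 h. Phase calls come from transcripts, free RNA in the droplets can enter them, and no measure of division is part of these data.

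**Figure D1:**
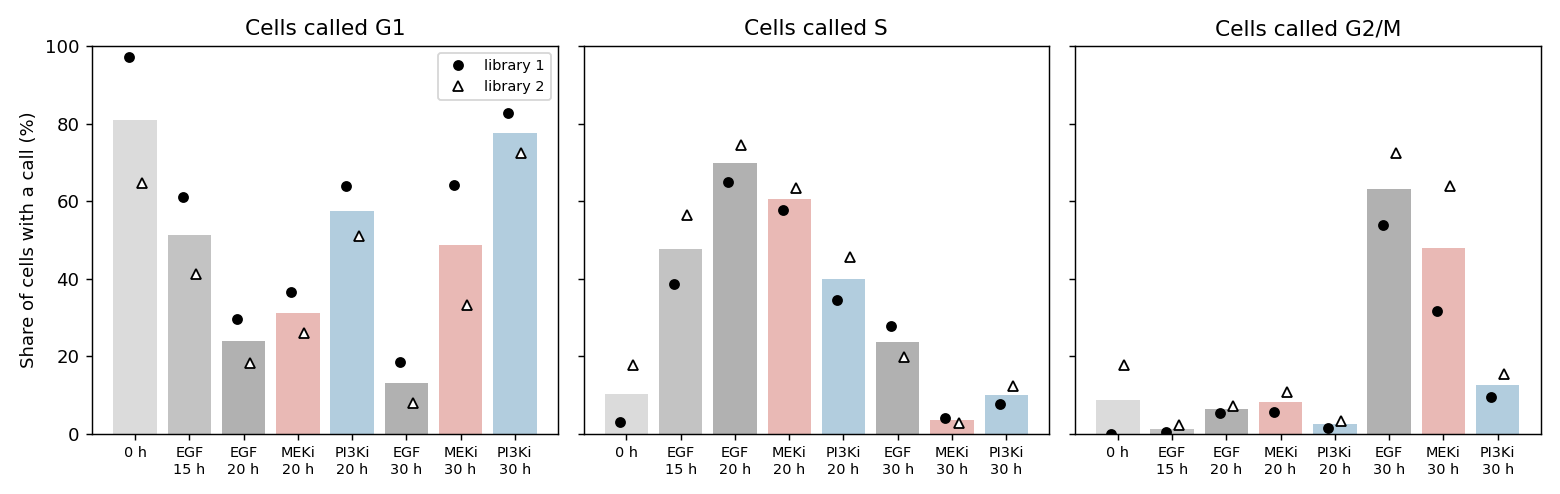
Share of cells called G1, S or G2/M (%, y axis of each panel) for the 8 conditions, at 6500 UMIs per cell; circles are library 1, triangles library 2 and bars their mean. At 30 h the S share is 3.45% with the MEK inhibitor, and the G1 share is 77.5% with the PI3K inhibitor against 13.2% with EGF alone.

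At 20 h the genes that report ERK signalling were lower with the MEK inhibitor than with EGF alone. DUSP4, a phosphatase that ERK induces and that acts back on it, was at 4.79 ± 0.369 CPM against 47.3 ± 0.991 with EGF alone (SD, n = 2), a log2 fold change of -3.32 (SE 0.21, adjusted p = 2.9e-17). The ERK phosphatase DUSP6 (-3.01), the receptor EPHA2 (-3.11), PHLDA1 (-2.61) and CCND1, which encodes cyclin D1 (-1.5), fell as well. Of the 10 measured MEK/ERK output genes 8 fell and 1 rose, the ephrin receptor EPHA4 (3.17); adjusted over the list alone 9 fell and 1 rose. MEK/ERK output genes had a list median of -2.34 (adjusted p = 6.1e-25; adjusted p = 0.0016 with an estimated correlation). CDKN1C, which encodes the CDK inhibitor p57, had the largest rise among genes at 20 CPM or more, from 9.77 ± 0.256 to 103 ± 31.3 CPM (log2 3.40, SE 0.18, adjusted p = 6.1e-21). CDKN2C, which encodes the CDK4/6 inhibitor p18, rose by 1.10, and CDK6 fell by 0.74. Here and below, a gene that is given only as an exception to the direction of its list, such as EPHA4, was chosen after its values were seen. The list of G1 cyclins and CDK inhibitors as a whole was not called, with 3 of 19 members higher and 4 lower, also adjusted over the list alone (median -0.02, adjusted p = 0.89), nor were the S phase list (adjusted p = 0.79) and the G2/M list (adjusted p = 0.12).

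Growth factor and early response genes were also lower with the MEK inhibitor at 20 h. The transcription factor genes MYC (-1.48, SE 0.13) and FOSL1 (-2.29, SE 0.24) and the ERK pathway inhibitor SPRED1 (-3.06, SE 0.36) were among 12 of 20 ERK-induced feedback and AP-1 genes that fell, while the antiproliferative gene BTG2 rose by 0.69. Adjusted over the list alone 12 fell and 2 rose. The median change of feedback and AP-1 genes was -0.78 (adjusted p = 3.5e-11; adjusted p = 0.033 with an estimated correlation). Among 5 EGFR ligands, secreted growth factors of the EGF family, 4 fell, led by AREG at 227 ± 1.15 against 633 ± 80.9 CPM (-1.49) and TGFA (-1.94); adjusted over the list alone all 5 fell. Among EGFR ligands the median was -1.83 (adjusted p = 1.3e-10; adjusted p = 0.013 with an estimated correlation). The calls of the other two, EREG (-1.83) and HBEGF (-2.02), were lost without the replicate block (adjusted p = 0.085 and 0.29). The nucleolar ribosome biogenesis genes RRP9 (-0.94), RRS1 (-0.95), NOP16 (-0.71) and WDR43 (-0.74) were among 17 of 22 members of that list that fell, or 18 adjusted over the list alone. The list of ribosome biogenesis genes had a median of -0.53 (adjusted p = 1.3e-14; adjusted p = 0.033 with an estimated correlation). Of 22 lysosome and autophagy genes 3 rose, or 5 adjusted over the list alone. Lysosome and autophagy genes had a list median of 0.23 (adjusted p = 0.035; adjusted p = 0.23 with an estimated correlation). The 3 that rose were SQSTM1 (0.48), TFEB (1.05) and LAMP2 (0.44), whose calls were lost without the replicate block (adjusted p = 0.087, 0.069 and 0.22).

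Largest rises and falls, here and below, are among called genes with a mean of at least 20 CPM in either condition and the same sign in both libraries. Outside the lists, the largest falls at 20 h with the MEK inhibitor included the transcriptional coactivator gene CITED4 (-3.28), the lipoprotein lipase inhibitor ANGPTL4 (-2.99) and the collagen receptor subunit ITGA2 (-2.71). The largest rises included the protocadherin PCDH9 (2.54), GPR1 (2.51), the exchange factor VAV3 (2.10) and KCNQ1OT1 (1.88), an antisense RNA of the imprinted region that also holds CDKN1C. Whether the counting used strand is not given in the sources used here, so KCNQ1OT1 reads cannot be told from those of KCNQ1. The fibroblast marker DCN was higher too, at 22.1 ± 8.25 against 11.4 ± 3.89 CPM (log2 1.01, adjusted p = 0.00072, and 0.46 without the replicate block). In all 1332 of 11147 genes changed at 20 h, 535 higher and 797 lower, and 342 without the replicate block. With library totals in place of composition scaling the split was 409 higher and 983 lower. DUSP4 lies on chromosome 8 (29333064 to 29350668, GRCh38), DUSP6 on chromosome 12 (89347232 to 89353271), CCND1 on chromosome 11 (69641087 to 69654474) and CDKN1C on chromosome 11 (2883213 to 2885773), all protein-coding; a count is per gene and does not resolve exons or UTRs.

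At 30 h ERK output was again lower with the MEK inhibitor, and single genes such as CDKN1C, CRYAB and KRT8 were higher. DUSP6 was at 2.16 ± 0.218 against 22.6 ± 0.590 CPM (log2 -3.32, SE 0.24, adjusted p = 2.1e-16) and CCND1 at 28.1 ± 4.24 against 104 ± 18.6 (-1.95). CDKN1C reached 196 ± 16.1 against 8.79 ± 2.87 CPM (4.54, SE 0.16, adjusted p = 7.7e-29). The small heat shock genes CRYAB (4.40) and HSPB1 (3.31), the collagen cross-linking enzyme LOX (3.61), the endocytic receptor LRP1 (3.56), the chloride channel BEST2 (4.82) and the noncoding RNA IGFL2-AS1 (4.28) rose. The keratins KRT8 (2.89), KRT15 (2.52) and KRT16 (3.54) and the surface glycoprotein CD24 (3.12) were higher as well. KRT16 is a keratin of stressed epidermis, and some of its reads could be shared with the related KRT17 (1.58). ACOX2, a peroxisomal oxidase, had the largest fall (-4.61), followed by DUSP6, ANGPTL4 (-3.26), DUSP4 (-3.12), PLEK2 (-2.79) and the ecto-nucleotidase NT5E (-2.66). HSPB1 lies on chromosome 7 (76302544 to 76304295), and KRT16 and KRT17 are neighbours on chromosome 17 (41609778 to 41615899 and 41619441 to 41624842).

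By list, 9 of 10 MEK/ERK output genes fell at 30 h and EPHA4 rose (3.8), also adjusted over the list alone. MEK/ERK output genes changed by a median of -2.52 (adjusted p = 1.7e-17; adjusted p = 0.019 with an estimated correlation). All 22 ribosome biogenesis genes fell, also adjusted over the list alone, among them BOP1 (-1.39), NOLC1 (-1.25) and the polyamine enzyme ODC1 (-1.47). Among ribosome biogenesis genes the median was -0.87 (adjusted p = 9.5e-21; adjusted p = 0.019 with an estimated correlation). Of 5 EGFR ligands 4 fell and EPGN rose (0.64), also adjusted over the list alone, with AREG at 162 ± 34.6 against 771 ± 1.21 CPM (-2.27). The list of EGFR ligands had a median of -1.63 (adjusted p = 0.003; adjusted p = 0.13 with an estimated correlation). Of 42 S phase genes 36 fell, also adjusted over the list alone, such as CLSPN (-1.79), CDC45 (-1.68), HELLS (-1.33) and FEN1 (-1.30). S phase genes had a list median of -0.83 (adjusted p = 1.6e-16; adjusted p = 0.11 with an estimated correlation). Of 21 FOXO targets and PI3K feedback genes 12 rose, including CITED2 (1.67), the muscle atrophy ubiquitin ligase FBXO32 (2.39), CCNG2 (1.23) and FOXO1 (1.00); adjusted over the list alone 14 rose and 1 fell. The median change of FOXO targets was 0.80 (adjusted p = 0.00029; adjusted p = 0.073 with an estimated correlation). Lysosome and autophagy genes rose in 13 of 22 cases, also adjusted over the list alone, led by GABARAPL1 (1.61) and WIPI1 (1.90). Among lysosome and autophagy genes the median was 0.36 (adjusted p = 0.0092; adjusted p = 0.13 with an estimated correlation). Feedback and AP-1 genes were not called at 30 h, with 7 of 20 higher and 8 lower, or 8 and 8 adjusted over the list alone (median -0.17, adjusted p = 0.16, but 0.04 without the replicate block).

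Differentiation lists moved by their members in different directions with the MEK inhibitor at 30 h. Of 18 squamous and keratinocyte stress genes 9 rose and 2 fell, the calcium-binding alarmins S100A8 (-1.87) and S100A9 (-2.40); adjusted over the list alone 10 rose and 2 fell. The list of squamous genes had a median of 0.99 (adjusted p = 0.013, but 0.11 without the replicate block and 0.09 by fry; adjusted p = 0.51 with an estimated correlation). Of 9 luminal genes 4 rose and KRT18 fell (-1.31), also adjusted over the list alone. Luminal genes had a list median of 0.41 (adjusted p = 0.0024; adjusted p = 0.11 with an estimated correlation). Mitochondrial-encoded transcripts rose in 12 of 13 cases, also adjusted over the list alone (median 0.33, adjusted p = 0.001; adjusted p = 0.47 with an estimated correlation), and MT-CYB (0.55) had an adjusted p of 0.074 without the replicate block. The basal list was not called by camera (7 of 14 higher and 6 lower, or 8 and 6 adjusted over the list alone; adjusted p = 0.17, but 0.019 by fry), although KRT15 and KRT5 (1.07) rose. Nor was the heat shock list, which holds HSPB1, with 3 of 10 members higher and 5 lower, also adjusted over the list alone (median -0.25, mean 0.12, adjusted p = 0.75). DCN was at 35.7 ± 21.9 against 10.2 ± 4.19 CPM (1.73, adjusted p = 4.4e-11). In all 4216 genes changed, 2103 higher and 2113 lower, and 2137 without the replicate block; with library totals only 1349 were higher and 3259 lower.

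With the PI3K inhibitor at 20 h, genes that FOXO transcription factors induce were higher and genes of DNA replication and mitosis lower than with EGF alone, but no list was called with an estimated correlation. TXNIP, a glucose-responsive inhibitor of thioredoxin, was at 354 ± 219 against 68.4 ± 25.2 CPM (log2 2.34, SE 0.12, adjusted p = 6e-21). The cyclin G2 gene CCNG2 (1.92), YPEL3 (1.93) and the insulin receptor substrate IRS2 (1.32) were among 11 of 21 FOXO targets and PI3K feedback genes that rose, with none lower, also adjusted over the list alone. FOXO targets changed by a median of 0.67 (adjusted p = 1.2e-09; adjusted p = 0.06 with an estimated correlation). The early response transcription factor gene EGR1 rose from 14.9 ± 3.90 to 78.6 ± 1.5 CPM (2.33, SE 0.16, adjusted p = 2.1e-16). It was among 11 of 20 feedback and AP-1 genes that rose, while FOSL1 fell (-0.58), also adjusted over the list alone (median 0.53, adjusted p = 5.5e-07; adjusted p = 0.093 with an estimated correlation); the rise of JUNB (0.75) had an adjusted p of 0.15 without the replicate block. CCND1 fell by 1.40 with this inhibitor too, but the MEK/ERK output list was not called, with 2 of 10 members higher and 1 lower, also adjusted over the list alone (median 0.40, adjusted p = 0.67).

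Of 42 S phase genes 36 fell at 20 h, among them FEN1 (-1.45), UHRF1 (-1.58), RRM2 (-1.30) and CLSPN (-1.06), or 37 adjusted over the list alone. Among S phase genes the median was -0.85 (adjusted p = 4.5e-25; adjusted p = 0.08 with an estimated correlation). Of 54 G2/M genes 40 fell, such as TMPO (-1.40), AURKA (-1.63) and CKS2 (-0.97), or 43 adjusted over the list alone. The list of G2/M genes had a median of -0.95 (adjusted p = 8.8e-25; adjusted p = 0.08 with an estimated correlation). Of 19 G1 cyclins and CDK inhibitors 10 fell, including CCNE2, which encodes cyclin E2 (-1.76), and 2 rose, CDKN1C (1.61) and CDKN1A (0.43); adjusted over the list alone 11 fell and 2 rose. G1 cyclins and CDK inhibitors had a list median of -0.55 (adjusted p = 6.5e-05; adjusted p = 0.075 with an estimated correlation). Of 22 ribosome biogenesis genes 15 fell, such as DKC1 (-0.94), NOP16 (-0.87), RRS1 (-1.13) and NOP58 (-0.79); adjusted over the list alone 16 fell and 1 rose. The median change of ribosome biogenesis genes was -0.47 (adjusted p = 1.3e-09; adjusted p = 0.08 with an estimated correlation). Sterol genes fell in 8 of 19 cases, led by SQLE (-0.87) and INSIG1 (-1.76), or 9 adjusted over the list alone. Among sterol genes the median was -0.27 (adjusted p = 0.00057; adjusted p = 0.26 with an estimated correlation). The basement membrane and hemidesmosome genes LAMB3 (1.11) and ITGB4 (0.67) were among 5 of 14 basal genes that rose, while ITGA6 fell (-0.27), also adjusted over the list alone. The list of basal genes had a median of 0.27 (adjusted p = 0.0038; adjusted p = 0.11 with an estimated correlation). The cathepsin gene CTSB (1.03), SQSTM1 (0.86) and GABARAPL1 (1.85) were among 5 of 22 lysosome and autophagy genes that rose, while GLA fell (-0.71), also adjusted over the list alone. Lysosome and autophagy genes had a list median of 0.11 (adjusted p = 0.0091; adjusted p = 0.093 with an estimated correlation). Heat shock genes fell in 4 of 10 cases, also adjusted over the list alone, including HSPH1 (-0.56) and HSPA1A (-1.06), whose reads can be shared with HSPA1B. Heat shock genes changed by a median of -0.28 (adjusted p = 0.0038; adjusted p = 0.16 with an estimated correlation).

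The largest rises at 20 h with the PI3K inhibitor were HIST1H2AC (3.50), a histone gene whose reads can be shared with its close copies, the adaptor GRB7 (3.30), FAM110C (2.78), the cell cycle regulator RGCC (2.67), CREBRF (2.62) and the amino acid transporter SLC7A2 (2.52). The largest falls were ZBED2 (-2.38), the nuclear lamin gene LMNB1 (-2.19), FGFBP1 (-2.03), the centromeric histone gene CENPA (-1.96), MCM10 (-1.90) and SH2D4A (-1.77). DCN was at 20.3 ± 6.29 against 11.4 ± 3.89 CPM (0.83, adjusted p = 0.0036, and 0.37 without the replicate block). In all 2607 genes changed, 1275 higher and 1332 lower, and 840 without the replicate block; with library totals only 796 were higher and 2177 lower. TXNIP lies on chromosome 1 (145992435 to 145996600) and EGR1 on chromosome 5 (138465490 to 138469315).

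At 30 h with the PI3K inhibitor, mitotic genes and genes of sterol and fatty acid synthesis were lower. Most genes of the basal list, LAMB3, LAMA3 and ITGB4 among them, were higher. The mitotic kinase AURKA was at 14.0 ± 4.74 against 111 ± 20.5 CPM (log2 -2.98, SE 0.14, adjusted p = 7.1e-23), with CENPF (-2.62), CDC20 (-2.70) and CKS2 (-2.16) among 53 of 54 G2/M genes that fell, also adjusted over the list alone. Among G2/M genes the median was -2.22 (adjusted p = 9.1e-107; adjusted p = 0.0058 with an estimated correlation). Of 42 S phase genes 36 fell, such as TYMS (-2.05) and FEN1 (-2.02), or 37 adjusted over the list alone. The list of S phase genes had a median of -1.11 (adjusted p = 3e-21; adjusted p = 0.036 with an estimated correlation). HMGCS1, the enzyme that makes HMG-CoA, was at 19.5 ± 5.77 against 72.6 ± 15.0 CPM (-1.90, SE 0.14, adjusted p = 6.7e-17). FDPS (-1.49), IDI1 (-1.5) and DHCR7 (-1.45) fell with it, and in all 16 of 19 sterol genes were lower, or 17 adjusted over the list alone. Sterol genes had a list median of -0.91 (adjusted p = 4.7e-15; adjusted p = 0.036 with an estimated correlation). Of 10 fatty acid synthesis genes 7 fell, including the elongase ELOVL6 (-2.05), the desaturase SCD (-1.55) and ACLY (-0.91), or 8 adjusted over the list alone. The median change of fatty acid genes was -0.82 (adjusted p = 0.00021; adjusted p = 0.046 with an estimated correlation).

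LAMB3, a laminin-332 chain, rose from 105 ± 11.3 to 576 ± 25.4 CPM (2.45, SE 0.11, adjusted p = 3e-24), with its integrin receptor subunit ITGB4 (1.92), LAMA3 (1.52) and KRT17 (1.77) among 10 of 14 basal genes that rose; KRT5 (-0.38) and KRT15 (-0.87) fell, also adjusted over the list alone. Among basal genes the median was 0.52 (adjusted p = 1.4e-09; adjusted p = 0.012 with an estimated correlation). EGR1 was at 73.3 ± 4.46 against 8.88 ± 2.75 CPM (3.11, SE 0.17, adjusted p = 2.8e-21) and JUNB at 230 ± 28.9 against 81.9 ± 30.0 (1.5). Of 20 feedback and AP-1 genes 15 rose and FOSL1 fell (-0.46), or 16 and 1 adjusted over the list alone. The list of feedback and AP-1 genes had a median of 0.76 (adjusted p = 4.4e-08; adjusted p = 0.054 with an estimated correlation). The EGFR ligand HBEGF rose by 2.13 and EPGN by 0.79; 4 of 5 ligands rose, also adjusted over the list alone. EGFR ligands had a list median of 0.74 (adjusted p = 0.03, but 0.13 without the replicate block; adjusted p = 0.18 with an estimated correlation). The other two, EREG (0.74) and AREG (0.41), had adjusted p = 0.18 and 0.35 without the block. EGFR itself rose from 122 ± 17.3 to 273 ± 5.75 CPM (1.16, SE 0.09, adjusted p = 2.7e-15). Of 21 FOXO targets 12 rose, including TXNIP (2.07), CITED2 (1.40), IRS2 (1.30) and CCNG2 (1.27), and CDKN1B fell (-0.56), or 13 and 1 adjusted over the list alone. FOXO targets changed by a median of 0.76 (adjusted p = 8.1e-05; adjusted p = 0.041 with an estimated correlation). The MEK/ERK output list was not called by camera with the PI3K inhibitor (adjusted p = 0.071, but 0.00042 by fry, median 0.45), with 4 of 10 members higher, also adjusted over the list alone, among them PHLDA1 (1.01) and DUSP6 (0.90), and ETV4 lower (-0.95).

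Smaller list changes at 30 h with the PI3K inhibitor were these. Glycolysis genes fell in 10 of 16 cases, including PGAM1 (-0.99), PGK1 (-0.84) and LDHA (-0.62), while PFKP (0.41) and GAPDH (0.33) rose, also adjusted over the list alone. Among glycolysis genes the median was -0.42 (adjusted p = 0.011; adjusted p = 0.22 with an estimated correlation). Ribosome biogenesis genes fell in 15 of 22 cases, such as NOP16 (-1.04) and NOLC1 (-0.91), and NPM1 rose (0.25), or 17 and 1 adjusted over the list alone. The list of ribosome biogenesis genes had a median of -0.42 (adjusted p = 9e-05; adjusted p = 0.11 with an estimated correlation). G1 cyclins and CDK inhibitors fell in 10 of 19 cases, led by the mitotic transcription factors FOXM1 (-2.28) and MYBL2 (-1.88), which the list also holds, and CDKN1C rose (1.38), also adjusted over the list alone. G1 cyclins and CDK inhibitors had a list median of -0.56 (adjusted p = 0.0038; adjusted p = 0.075 with an estimated correlation). YAP/TEAD targets rose in 4 of 10 cases, led by the receptor kinase AXL (1.45), and F3 fell (-0.53, adjusted p = 0.32 without the replicate block), also adjusted over the list alone. The median change of YAP/TEAD targets was 0.45 (adjusted p = 0.047, but 0.13 without the replicate block; adjusted p = 0.11 with an estimated correlation). Heat shock genes fell in 5 of 10 cases, also adjusted over the list alone, led by HSPE1 (-1.46) and HSP90AA1 (-1.19). Among heat shock genes the median was -0.43 (adjusted p = 0.0011; adjusted p = 0.11 with an estimated correlation). The mitophagy receptor BNIP3L (3.28), RGCC (3.37) and KRT16 (2.67) had the largest rises beside EGR1, and ACOX2 (-3.28), FAM83D (-3.16), LMNB1 (-3.14) and CENPA (-3.05) the largest falls. DCN, at 12.5 ± 8.0 against 10.2 ± 4.19 CPM, did not pass the test (adjusted p = 0.45). In all 4428 genes changed, 2201 higher and 2227 lower, and 2384 without the replicate block; with library totals only 1268 were higher and 3688 lower. HMGCS1 lies on chromosome 5 (43289395 to 43313512), LAMB3 on chromosome 1 (209614870 to 209652466), EGFR on chromosome 7 (55019021 to 55211628) and AURKA on chromosome 20 (56369389 to 56392337).

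**Figure D2:**
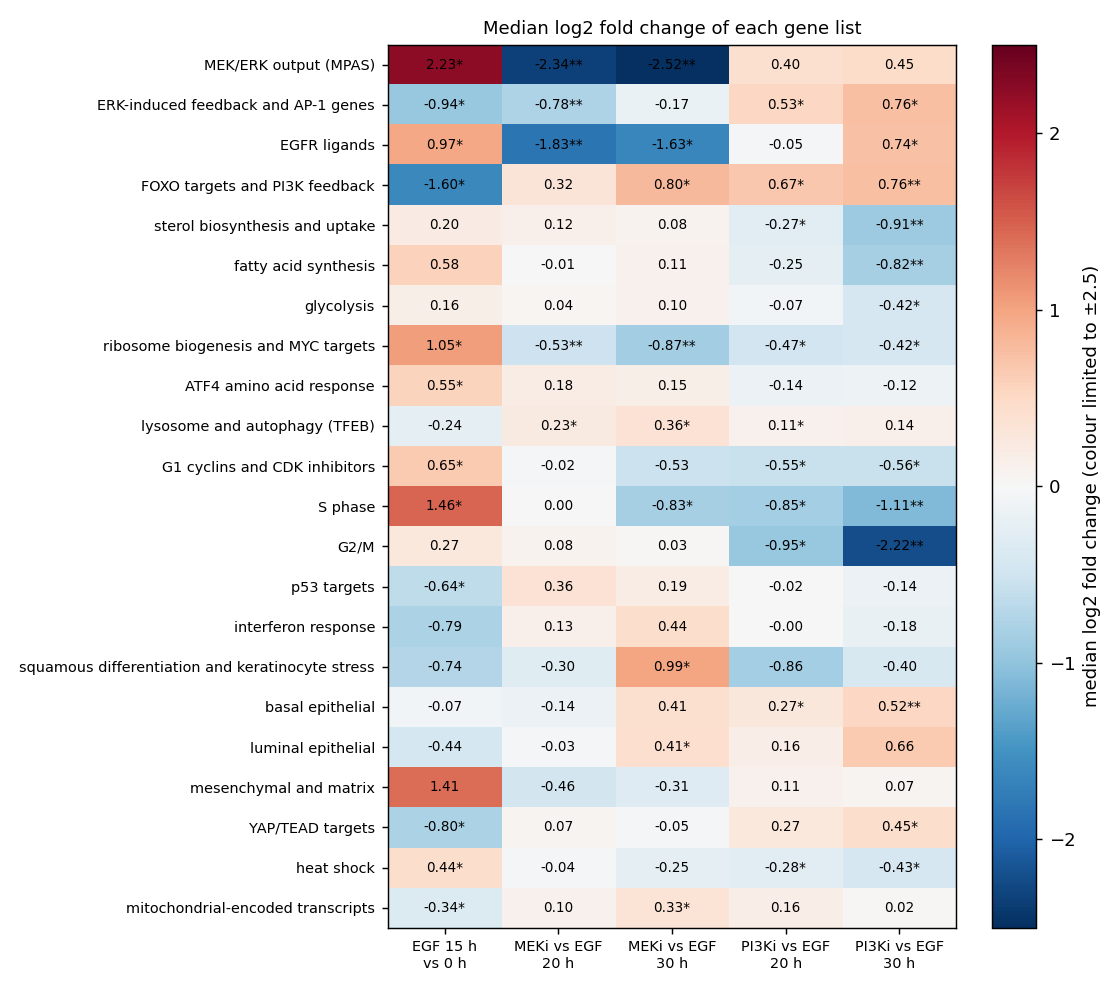
Median log2 fold change of the members of each gene list (colour). The first column is EGF alone at 15 h against unstimulated cells, and the others are the inhibitors against EGF alone at 20 h and 30 h. A star marks a list called by camera and a double star a list also called with an estimated correlation. The G2/M list stands at -2.22 with the PI3K inhibitor at 30 h, and the MEK/ERK output list at -2.34 and -2.52 with the MEK inhibitor.

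Some lists were not called by camera in any of the 4 comparisons with EGF alone. Interferon response genes had medians from -0.18 to 0.44 with the smallest adjusted p at 0.37, although fry, which does not compare a list with other genes, called them higher with the MEK inhibitor (0.041) and lower with the PI3K inhibitor (0.02) at 30 h. Mesenchymal and matrix genes had medians from -0.46 to 0.11 with the smallest adjusted p at 0.38. The p53 target list had its smallest adjusted p at 0.14 with the MEK inhibitor at 20 h (median 0.36, 6 of 20 higher and 3 lower, or 7 and 3 adjusted over the list alone). The list of amino acid response genes that ATF4 induces reached 0.10, and 0.0025 by fry, with the PI3K inhibitor at 30 h (median -0.12, 1 of 19 higher and 6 lower, also adjusted over the list alone), where PSAT1 fell by 1.78. In that list the MEK and PI3K inhibitors parted at the amino acid transporter SLC3A2, which rose at 30 h with the former (1.02) and fell with the latter (-0.86). Fry also called lists that camera did not call in the comparison at hand. These were FOXO targets with the MEK inhibitor at 20 h (0.031), fatty acid (0.041) and luminal genes (0.049) with the PI3K inhibitor at 20 h, and luminal (0.005) and lysosome genes (0.0015) with it at 30 h. With the MEK inhibitor at 30 h they were G1 cyclins and CDK inhibitors (0.019) and YAP/TEAD targets (0.023). Of the markers of other cell types, DCN had 19.6 and CD68 5.14 CPM over all cells. PECAM1 had 0.633, and the highest of the rest, HBA1, had 0.114.

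Among the direct targets and pathway members, MAP2K1, which encodes MEK1, was lower with the MEK inhibitor at 20 h (-0.72, adjusted p = 0.00082) and 30 h (-1.14, adjusted p = 4.5e-09), and MAPK3, which encodes ERK1, was higher at 30 h, at 10.8 ± 1.12 against 3.22 ± 1.19 CPM (1.63). PIK3CA, a catalytic subunit of PI3K, was higher with the PI3K inhibitor at 20 h (0.71, adjusted p = 0.0047) and 30 h (0.76, adjusted p = 0.0007), and AKT1 was lower at 30 h with either inhibitor (-0.54 with MEK and -0.47 with PI3K inhibition). EGFR did not pass the test with the MEK inhibitor (-0.27 and -0.23 at 20 h and 30 h). Its rise at 20 h with the PI3K inhibitor (0.44) had an adjusted p of 0.094 without the replicate block. PIK3R1 was lower in all 4 comparisons (-0.54 to -0.43), with adjusted p from 0.16 to 0.36 without the block. AKT2 and PIK3CB did not pass the test in any of the 4.

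**Figure D3:**
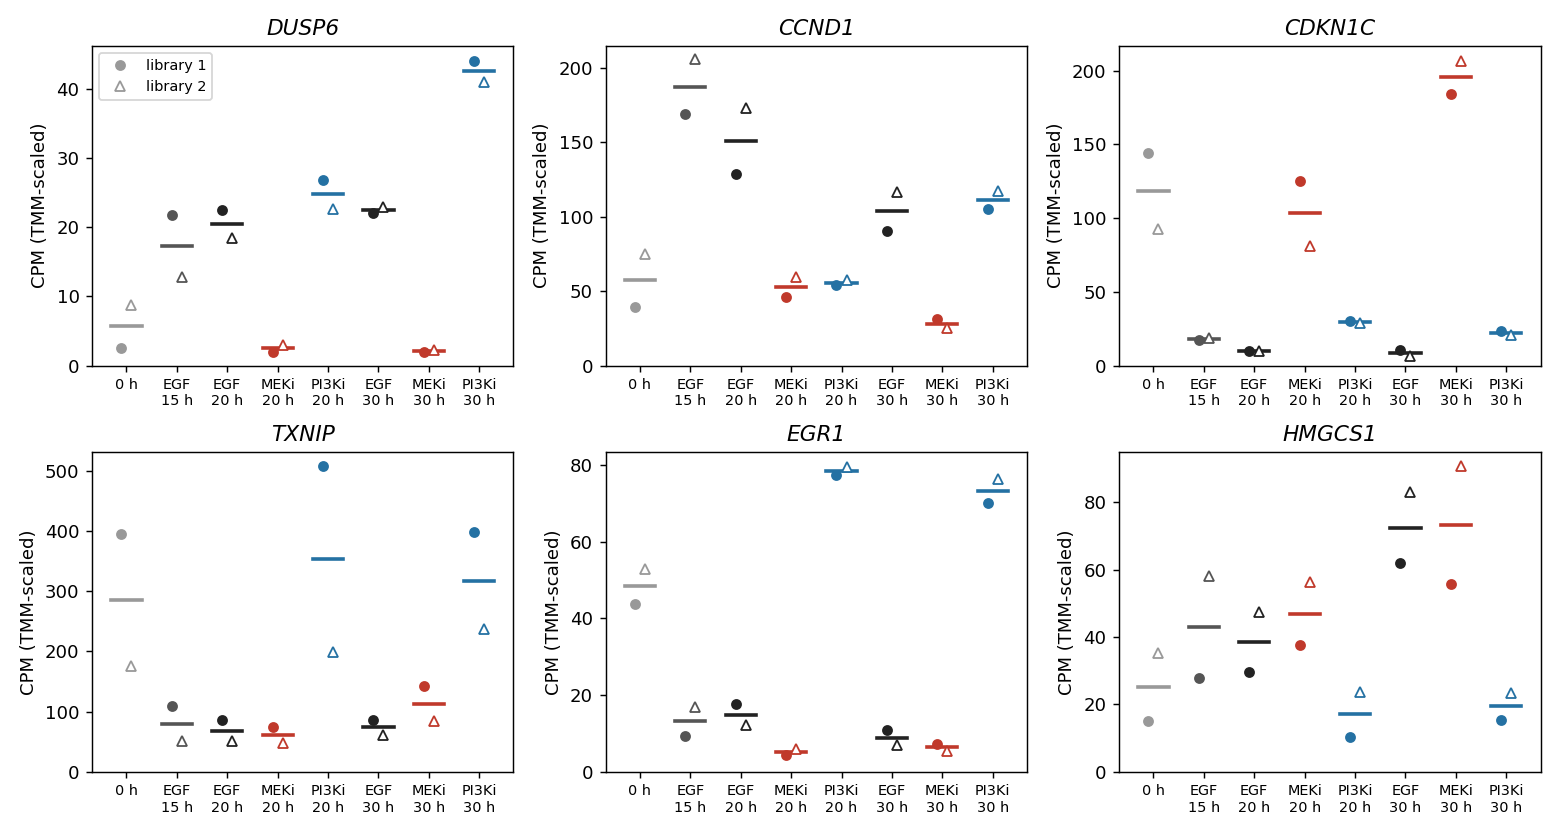
TMM-scaled CPM (y axis, linear) of DUSP6, CCND1, CDKN1C, TXNIP, EGR1 and HMGCS1 in the 8 conditions, with points for the libraries and bars for their mean. DUSP6 is at 2.16 CPM with the MEK inhibitor at 30 h against 22.6 with EGF alone, and HMGCS1 at 19.5 with the PI3K inhibitor against 72.6.

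Tested directly against each other, the inhibitors differed in ERK output, early response and mitotic genes. At 30 h DUSP6 was at 2.16 ± 0.218 CPM with the MEK inhibitor and 42.7 ± 2.20 with the PI3K inhibitor (log2 -4.23, SE 0.21, adjusted p = 7e-23), and RGCC (-4.55), FAM110C (-3.71) and ANGPTL4 (-3.61) lay lower with the MEK inhibitor. The helicase PIF1 (6.15), the serpin SERPINB13 (5.03), NEURL1B (4.55) and IGFL2-AS1 (4.52) lay higher. EGFR was lower with the MEK than with the PI3K inhibitor at 20 h (-0.70) and 30 h (-1.39, SE 0.09), as was PIK3CA (-0.95 and -0.79). At 20 h GRB7 (-5.34), FAM110C (-4.62), the transcription factor FOXC2 (-4.52) and RGCC (-4.02) were lower and GPR1 (3.35), SERPINB13 (3.29) and GMPR (3.25) higher with the MEK inhibitor.

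MEK/ERK output genes were lower with the MEK inhibitor in 8 of 10 cases at 20 h with 1 higher, and in 9 of 10 at 30 h, the same counts adjusted over the list alone (medians -3.07 and -3.05; adjusted p = 0.0055 and 0.015 with an estimated correlation). Feedback and AP-1 genes were lower in 14 and 13 of 20 cases, or 16 and 15 adjusted over the list alone (medians -1.23 and -0.97; adjusted p = 0.0055 and 0.036 with an estimated correlation), and EGFR ligands in 4 of 5 at both times, also adjusted over the list alone (medians -1.44 and -1.91; adjusted p = 0.046 and 0.064 with an estimated correlation). G2/M genes were higher with the MEK inhibitor in 40 and 51 of 54 cases, or 44 and 51 adjusted over the list alone (medians 1.10 and 2.23; adjusted p = 0.046 and 0.015 with an estimated correlation). S phase genes were higher at 20 h in 33 of 42 cases, or 37 adjusted over the list alone (median 0.83; adjusted p = 0.055 with an estimated correlation). At 30 h 18 of 19 sterol genes were higher with the MEK inhibitor, also adjusted over the list alone (median 1.10; adjusted p = 0.06 with an estimated correlation). In all 2410 genes differed at 20 h, 1248 higher and 1162 lower with the MEK inhibitor, and 4632 at 30 h, 2366 higher and 2266 lower. Without the replicate block the counts were 999 and 2703, and with library totals only the split at 20 h was 1687 higher and 907 lower.

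After 15 h of EGF alone DUSP4, CCND1 and other genes differed from unstimulated cells, while no list was called with an estimated correlation. DUSP4 was at 62.7 ± 3.71 against 8.31 ± 6.98 CPM (log2 3.61, SE 0.35, adjusted p = 9.8e-12), CCND1 at 187 ± 26.1 against 57.4 ± 25.1 (1.94) and the serine synthesis enzyme PHGDH at 97.4 ± 4.81 against 6.53 ± 3.26 (4.25). Asparagine synthetase, ASNS (3.0), the cell cycle transcription factor E2F1 (3.72) and the replication factor GINS2 (4.09) rose. CDKN1C fell by 2.96, with the FOXO targets FBXO32 (-6.05), TXNIP (-1.83) and YPEL3 (-2.96), the small heat shock gene HSPB1 (-2.67) and S100A7 (-8.21). DCN was at 11.8 ± 8.58 against 99.0 ± 15.1 CPM (-2.76, adjusted p = 1.7e-14). Only 29 unstimulated cells and 64 cells at 15 h stood for library 2, and 90.9% of called genes had the same sign in both libraries. No cells without EGF were measured at 15 h, so EGF and time in culture cannot be told apart in this comparison.

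In this comparison 12 lists were called by camera with the preset correlation and 17 by fry; with an estimated one their adjusted p lay between 0.16 and 0.31. The MEK/ERK output list rose in 7 of 10 cases, or 8 adjusted over the list alone (median 2.23), and EGFR ligands in 3 of 5, also adjusted over the list alone (0.97). Ribosome biogenesis genes rose in 19 of 22 cases, or 20 adjusted over the list alone (1.05), and S phase genes in 29 of 42, or 32 adjusted over the list alone (1.46). ATF4 genes rose in 10 of 19 cases with 3 lower, or 11 and 3 adjusted over the list alone (0.55), and G1 cyclins and CDK inhibitors in 8 of 19 with CDKN1C lower, also adjusted over the list alone (0.65). Heat shock genes rose in 5 of 10 cases with 2 lower, or 6 and 2 adjusted over the list alone (0.44), a call lost without the replicate block (adjusted p = 0.15). FOXO targets fell in 13 of 21 cases, or 14 adjusted over the list alone (-1.60), feedback and AP-1 genes in 12 of 20 with 4 higher, or 13 and 4 adjusted over the list alone (-0.94), among them DUSP1 (-1.44) and BTG2 (-2.25). p53 targets fell in 10 of 20 cases with 2 higher, or 10 and 3 adjusted over the list alone (-0.64), YAP/TEAD targets in 5 of 10 with 1 higher, also adjusted over the list alone (-0.80), and mitochondrial-encoded transcripts in 9 of 13, or 10 adjusted over the list alone (-0.34). In all 3116 genes changed, 1567 higher and 1549 lower, and 1877 without the replicate block; with library totals only 2260 were higher and 1152 lower.

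From 20 h to 30 h mitotic transcripts rose in cells with EGF alone, and S phase transcripts fell, a list call that was lost with an estimated correlation. The mitotic kinase gene PLK1 (2.41), CDKN3 (2.21), CENPF (2.15) and DLGAP5 (2.15) rose, and CCNE2 (-2.11), FAM111B (-2.04) and the cornified envelope genes SPRR2D (-3.54) and SPRR1B (-2.23) fell. Of 54 G2/M genes 51 rose, or 52 adjusted over the list alone (median 1.28; adjusted p = 0.00089 with an estimated correlation), and 26 of 42 S phase genes fell with 1 higher, or 28 and 2 adjusted over the list alone (median -0.65; adjusted p = 0.07 with an estimated correlation). Sterol genes rose in 15 of 19 cases, or 19 adjusted over the list alone (median 0.73; adjusted p = 0.0056 with an estimated correlation). In all 868 genes changed, 503 higher and 365 lower, and 165 without the replicate block. Within the MEK inhibitor 2369 genes changed between the times, 1334 higher and 1035 lower, and 802 without the block; with library totals only 922 were higher and 1569 lower. There 39 of 42 S phase genes fell and 49 of 54 G2/M genes rose, the same counts adjusted over the list alone (medians -1.38 and 1.09; adjusted p = 0.017 and 0.022 with an estimated correlation). Within the PI3K inhibitor 1236 genes changed, 612 higher and 624 lower, and 164 without the block; with library totals only 428 were higher and 902 lower. There 25 of 42 S phase genes fell, or 32 adjusted over the list alone (median -0.80; adjusted p = 0.025 with an estimated correlation), while the G2/M list was not called, and 4 of 10 YAP/TEAD targets rose, also adjusted over the list alone (median 0.72; adjusted p = 0.025 with an estimated correlation).

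The change with an inhibitor was tested for a difference between 30 h and 20 h. It differed for 622 genes with the MEK inhibitor, 325 with a more positive change at 30 h and 297 with a more negative one, and for 630 genes with the PI3K inhibitor, 268 and 362. Without the replicate block these counts were 36 and 6, and with library totals only the splits were 214 and 622 for MEK and 195 and 591 for PI3K.

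Within G1-called cells, where the share of S and G2/M cells is held out, ERK output fell with the MEK inhibitor and sterol genes fell with the PI3K inhibitor at 30 h. All 7 testable MEK/ERK output genes fell with the MEK inhibitor at 30 h (median -2.52; adjusted p = 0.0035 with an estimated correlation), and 12 of 22 ribosome biogenesis genes (median -0.81; adjusted p = 0.0055 with an estimated correlation). With the PI3K inhibitor at 30 h 11 of 19 sterol genes (median -0.90) and 11 of 19 p53 target genes (median -1.18) fell, each with adjusted p = 0.0032 with an estimated correlation. The p53 target list also fell with the MEK inhibitor at 30 h in 7 of 19 cases (median -0.64; adjusted p = 0.03 with an estimated correlation), and FOXO targets rose with the PI3K inhibitor at 20 h in 4 of 18 cases (median 0.60; adjusted p = 0.028 with an estimated correlation). Squamous genes fell with the PI3K inhibitor at 20 h in 8 of 16 cases (median -1.25; adjusted p = 0.14 with an estimated correlation) and at 30 h in 7 of 16 with 1 higher (median -1.71; adjusted p = 0.11 with an estimated correlation). In these sums 330 and 714 genes changed with the MEK inhibitor at 20 h and 30 h, and 718 and 802 with the PI3K inhibitor. The ligand EPGN (-0.18), AKT1 (0.0029) and DCN (-1.41, adjusted p = 0.0039) turned direction in G1 cells with the PI3K inhibitor at 30 h, and FAM83D had counts near 0 in these cells. With EGF alone at 30 h only 41 and 26 cells of libraries 1 and 2 were called G1, and both inhibitors were compared with these same cells. List calls that were lost in G1 cells were those of EGFR ligands (adjusted p = 0.25), ribosome biogenesis (0.17) and YAP/TEAD targets (0.14) with the PI3K inhibitor at 30 h, basal genes with it at 20 h (0.15) and squamous genes with the MEK inhibitor at 30 h (0.48). Phase calls rest on the S phase and G2/M lists, so neither these lists nor their members are read in these cells.

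The changes of the inhibitors overlapped, although both were measured against the same EGF-alone sums. Across 11147 genes, which are not independent replicates, the log2 fold changes correlated with r = 0.25 (rho 0.293) at 20 h and 0.357 (rho 0.417) at 30 h, while simulated unchanged conditions against those controls gave r = 0.372 and 0.537. Their covariance was 0.0944 at 20 h and 0.200 at 30 h, against 0.0441 and 0.0451 in 100 simulated draws, a difference of 0.0503 and 0.155. At 30 h 866 genes were higher and 1010 lower with both inhibitors, where independent lists would share 415 and 422, and 406 went in opposite directions against 837. At 20 h these counts were 149 against 61.2, 297 against 95.2 and 125 against 155. Between changes taken from different libraries, which share no control sum, r was 0.133 and 0.123 at 20 h and 0.329 and 0.233 at 30 h. Within a library it was 0.262 and 0.344 at 20 h and 0.409 and 0.377 at 30 h, so a positive relation was left without shared controls.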

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

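The tests of heat shock genes, of doublets and of cells lost to an upper limit on detected genes were chosen after the results were seen; the other tests in this part were set before. The values in the paragraphs on the change of genes were picked out because an inhibitor's change differed between 20 h and 30 h by an interaction test, except for the G2/M shares, whose difference was not tested. The S share with the MEK inhibitor and the unstimulated cells of library 2 were weighed because their phase shares stood out, without such a test.

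With the MEK inhibitor the change of 622 genes differed between the times. Luminal genes (median of the members' changes at 30 h minus 20 h, log2 1.10; adjusted p = 0.054 with an estimated correlation), squamous genes (0.94; 0.24), FOXO targets (0.48; 0.12), feedback and AP-1 genes (0.41; 0.19) and mitochondrial-encoded transcripts (0.25; 0.37) had more positive changes at 30 h. S phase genes (-0.90; 0.054), G1 cyclins and CDK inhibitors (-0.37; 0.094) and ribosome biogenesis genes (-0.36; 0.082) had more negative ones, and basal genes differed with a median of 0.052 (0.094). Without the replicate block the calls of basal genes (adjusted p = 0.069) and mitochondrial-encoded transcripts (0.051) were lost, and by fry those of squamous genes (0.19), AP-1 genes (0.11) and mitochondrial-encoded transcripts (0.06). Genes called in opposite directions at the times numbered 7. In order of the adjusted p of the interaction they were led by the zinc transporter SLC39A10, at 0.84 and -0.56, and the stress gene NDRG1, at -0.71 and 0.51, both named after their values were seen.

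With the PI3K inhibitor the change of 630 genes differed. G2/M genes had a more negative change at 30 h (-1.19; adjusted p = 0.016 with an estimated correlation), as had sterol genes (-0.54; 0.065), fatty acid synthesis genes (-0.47; 0.065), S phase genes (-0.28; 0.35) and glycolysis genes (-0.19; 0.32). EGFR ligands (0.57; 0.065), basal genes (0.46; 0.016), YAP/TEAD targets (0.44; 0.065) and feedback and AP-1 genes (0.25; 0.32) had more positive ones; the calls of YAP/TEAD targets and AP-1 genes were lost without the replicate block (adjusted p = 0.102 and 0.10). By fry those of AP-1 genes (0.19), S phase genes (0.15) and glycolysis genes (0.061) were lost. Genes called in opposite directions numbered 22, led in the same order by SLC39A10, at 0.82 and -1.02, and ARL6IP1, at 0.48 and -1.06, named after their values were seen. The mean G2/M share with the MEK inhibitor minus that with EGF alone was 1.91 points at 20 h and -15.2 points at 30 h, positive in both libraries at the first time and negative in both at the second, which was not tested. These signs depend on how phases were called. With calls from list shares the 20 h difference was negative in both libraries (10.4% against 12.4% and 0.893% against 1.02%), and that at 30 h was positive in library 2 (51.5% against 48.6%). At 20 h it was also negative in library 2 without thinning (12.3% against 14.2%), and in library 1 without the top 5% of cells by UMIs (5.88% against 6.31%) or without cells above 4000 detected genes (5.46% against 5.99%).

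Of 20 feedback and AP-1 genes 15, EGR1 and JUNB among them, were higher with the PI3K inhibitor at 30 h and FOSL1 was lower; the list's call was lost with an estimated correlation (adjusted p = 0.054). The median change of 4 inducible heat shock genes was -0.43, with HSPA1A at -0.60 and HSPH1 at -0.45, while HSPA1B (-0.40) and DNAJB1 (-0.10) did not pass the test. Since the heat shock list fell with this inhibitor at both times, these values cannot decide whether handling stress played a part. With library totals only the list's median was 0.52, against composition scaling as the whole cause. Within G1 cells the fitted median was 0.51. By library, from CPM scaled to library totals and not as in the fit, it was 0.686 and 0.278 in libraries 1 and 2. Over all cells the same measure gave 0.588 and 0.379. The libraries differ too much within G1 cells to tell a larger share of G1 cells from a change within cells. PI3K inhibition itself stays open as the biological explanation.

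Few cells were called S and many G2/M with the MEK inhibitor at 30 h. In called cells at or below the median UMIs of their condition and library, the S share difference to EGF alone was at least 1.04 times that in all called cells in either library. The deeper cells left out were more than the doublets that the tag shares predict in these conditions (at most 22.4% of single-tagged cells). Whether doublets lie among the deeper cells was not shown. The split also moved the S share with EGF alone, from 27.8% to 39.3% in library 1 and from 19.7% to 21.5% in library 2. It therefore cannot decide on doublets. All 76 and 287 single-tagged cells with EGF alone that the count tables do not hold were then counted as not S. The difference of the S share with the MEK inhibitor to EGF alone was still -16.6 and -7.65 points. Exact binomial 95% intervals of the shares did not meet, but they cover the sampling of cells and not the spread between replicates. Even so counted, the S share with the MEK inhibitor lay lower in both libraries. That argues against a loss of EGF-alone cells to an upper limit on detected genes as the whole cause of the lower S share. Whether such a limit removed cells, and what that did to the G2/M shares, was not tested. All 58 and 194 single-tagged cells with the MEK inhibitor that the count tables do not hold were then counted as S. The S share with the MEK inhibitor then lay 8.92 points lower than with EGF alone in library 1 but 7.83 points higher in library 2. A loss of S cells with the MEK inhibitor thus stays open. In G2/M cells DUSP6, DUSP4, EPHA2 and PHLDA1 kept a median of 11% of their level with EGF alone. That argues against wrongly tagged EGF-alone cells, or free RNA from such cells, as most of what was counted there. A minority of such cells or some free RNA could leave a remainder of this size and is not excluded. Cells with the MEK inhibitor at 20 h could not be told apart by DUSP6, which was about as low there (1.94 and 3.01 CPM in libraries 1 and 2). Cells past the G1/S boundary at 15 h may have gone on to G2/M while fewer cells entered S. This stays open beside doublets, a loss of S cells, some wrongly tagged cells and free RNA, untested, since entry was not measured.

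The unstimulated cells of library 2 were unlike those of library 1, with 64.7% against 97.1% called G1. The count tables held 29 of 127 single-tagged unstimulated cells of library 2 (22.8%) and 175 of 235 of library 1 (74.5%). What the missing cells did to these shares was not tested. They lay 0.170 of the way to 15 h of EGF for the lower of risers and fallers, and S or G2/M cells lay 0.235 further than G1 cells. The first value rests on 29 cells and the second on 6 and 11, and both on genes with an absolute log2 change above 2 and at least 50 CPM, a selection made after the data were seen. Over 9 selections of genes they ran from -0.058 to 0.240 and from 0.176 to 0.539, so cells of other conditions with the unstimulated tag and free RNA cannot be told apart at this number of cells. The values predicted for free RNA were met in 0 of the 9 selections and those against it in 5, while those for cells of other conditions were met in 3 and those against them in 1. No biological explanation was tested.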

How the results depend on the processing

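Alternatives that were added later are the sums over S and G2/M cells, the fit without the unstimulated and 15 h cells, the limit of 4000 detected genes, list calls with library totals and inhibitor changes from different libraries. The counts of changed genes stayed within 1.5 times for all 12 comparisons with RLE size factors, library totals only, no low-count filter, at least 10 CPM in 2 sums, either cell filter, no cells among the top 5% by UMIs and an absolute log2 change of at least 0.5, and for 11 of 11 without the unstimulated and 15 h cells. The cell filters removed 0 cells, so they show nothing about stability.

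Without the replicate block the counts were 342 for MEK against EGF at 20 h, 840 for PI3K against EGF at 20 h, 2137 for MEK against EGF at 30 h, 2384 for PI3K against EGF at 30 h, 999 for MEK against PI3K at 20 h, 2703 for MEK against PI3K at 30 h, 1877 for 15 h of EGF, 165 for time with EGF, 802 for time with the MEK inhibitor, 164 for time with the PI3K inhibitor, 36 for MEK by time and 6 for PI3K by time. With 29 cells in every sum, which leaves fewer UMIs, they were 33 for MEK against EGF at 20 h, 178 for PI3K against EGF at 20 h, 570 for MEK against EGF at 30 h, 804 for PI3K against EGF at 30 h, 224 for MEK against PI3K at 20 h, 842 for MEK against PI3K at 30 h, 687 for 15 h of EGF, 94 for time with EGF, 266 for time with the MEK inhibitor, 61 for time with the PI3K inhibitor, 18 for MEK by time and 20 for PI3K by time. With cells thinned to 6500 UMIs, which also lowers depth, they were 575 for MEK against EGF at 20 h, 1570 for PI3K against EGF at 20 h, 2750 for MEK against EGF at 30 h, 2932 for PI3K against EGF at 30 h, 1302 for MEK against PI3K at 20 h, 401 for time with EGF, 1398 for time with the MEK inhibitor, 587 for time with the PI3K inhibitor, 281 for MEK by time and 268 for PI3K by time. In G1 cells, with fewer cells and 8491 genes tested, they were 330 for MEK against EGF at 20 h, 718 for PI3K against EGF at 20 h, 714 for MEK against EGF at 30 h, 802 for PI3K against EGF at 30 h, 904 for MEK against PI3K at 20 h, 2929 for MEK against PI3K at 30 h, 47 for time with EGF, 531 for time with the MEK inhibitor, 583 for time with the PI3K inhibitor, 31 for MEK by time and 44 for PI3K by time. In S and G2/M cells they were 1312 for PI3K against EGF at 20 h, 2392 for PI3K against EGF at 30 h, 1410 for MEK against PI3K at 20 h, 2960 for MEK against PI3K at 30 h, 673 for time with the PI3K inhibitor and 277 for PI3K by time. With DESeq2 they were 796 for MEK against EGF at 20 h, 485 for time with EGF, 377 for MEK by time and 412 for PI3K by time, and with only the conditions compared 2065 for 15 h of EGF and 1515 for time with EGF; where construction does not show it, the cause was not tested.

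With an estimated correlation the called lists numbered 0 for PI3K against EGF at 20 h, 2 for MEK at 30 h, 6 for PI3K at 30 h and 0 for 15 h of EGF. In G1 cells 7 lists were called for 15 h of EGF. The correlation of the inhibitors' changes was 0.342 at 20 h and 0.442 at 30 h in G1 cells. Both changes share the EGF-alone sums there too, and unchanged conditions were not simulated for sums over G1 cells. How much the shared sums add to these values is therefore not known, and the cause was not tested. Between changes from different libraries it was on average 0.128 and 0.281, where no control sum is shared and single libraries are noisier. Without thinning the G2/M share was 10.3% with EGF and 3.96% with the PI3K inhibitor at 20 h, and the S share 2.32% with the MEK inhibitor at 30 h. With calls from list shares the S share was 51.7%, 46.8% and 19.3% at 20 h with EGF, the MEK and the PI3K inhibitor, and 16.5%, 2.44% and 2.7% at 30 h, with a G2/M share of 6.05% for the last. Its G1 shares with EGF alone were 41.4% and 41.8% at 20 h and 25.6% and 32.3% at 30 h in libraries 1 and 2. Leaving out 1 of 2 libraries moves a share by less than 1 SD by construction and allows no test.

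Of named genes' log2 changes, 586 kept direction and call with RLE, 554 with DESeq2 (30 lost and 2 gained the call), 452 without the block (134 lost it), 544 with library totals (19 lost and 15 gained it) and 379 in G1 cells (129 lost and 1 gained it). The direction turned for 35 in G1 cells and 8 with library totals, and for 4 without replicate 1 and 2 without replicate 2, which have no test. The log2 values in G1 cells follow. In MEK against EGF at 20 h they were 0.0278 for AKT1, 0.0364 for AKT2, -0.75 for ISG15, 0.33 for PIK3CA and -0.64 for PIK3CB. In MEK against PI3K at 20 h they were -0.0555 for AKT1, 0.0138 for MAP2K2, -0.45 for PIK3CB and 0.20 for PIK3R1. In PI3K against EGF at 20 h they were 0.0832 for AKT1 and 0.0910 for AKT2. In PI3K against EGF at 30 h they were 0.00289 for AKT1, 0.37 for CDKN2C, 0.71 for CENPF, -0.0821 for CYR61, -1.41 for DCN, -0.18 for EPGN, 5.31 for FAM83D, 0.27 for FEN1, 1.27 for PIK3CB, 0.0604 for PSMB8, 0.59 for RRM2 and 0.17 for UHRF1. In MEK against EGF at 30 h they were -0.40 for AKT2, 0.12 for ELOVL6, 0.28 for FEN1, 0.14 for PIK3CA and 1.51 for PIK3CB. In time with EGF they were -0.68 for CENPF, -0.25 for DLGAP5, 0.14 for MAP2K1, 0.0830 for MAP2K2, -0.0308 for MAPK3, -1.47 for PIK3CB and 0.22 for PIK3R1. FAM83D counts in G1 cells are near 0, and CENPF, DLGAP5, FEN1, RRM2 and UHRF1 belong to the lists behind the phase calls, so their direction in G1 cells is not read. With library totals the values that turned follow, where a shift of all genes moves small changes past 0. In MEK against EGF at 30 h it was -0.14 for AKT2. In 15 h of EGF it was 0.0762 for AKT2. In PI3K against EGF at 20 h it was -0.0540 for CD68. In PI3K against EGF at 30 h it was -0.00429 for DCN. In MEK against PI3K at 20 h they were 0.0156 for MAP2K2 and 0.00797 for PIK3R1. In time with EGF it was 0.00885 for MAP2K2. In MEK against EGF at 20 h it was -0.0103 for PIK3CB. With either replicate left out, the range was for COL1A1 from -3.08 to 1.90 in 15 h of EGF, ISG15 from -1.74 to 0.26 in 15 h of EGF and MAP2K1 from -0.0516 to 1.04 in 15 h of EGF. It was for MT-ND6 from -1.01 to 0.13 in PI3K against EGF at 30 h, SPRR2A from -2.90 to 0.16 in MEK against EGF at 20 h and SPRY2 from -0.13 to 1.23 in PI3K against EGF at 20 h. Apart from library totals, the cause was not tested. Depth limits the unstimulated and 15 h cells of library 2 most, which hold 29 and 64 cells.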

Other observations

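The correlations of the EGF response with the changes by either inhibitor over all cells, and those at 20 h, were chosen after their values were seen; the tests within G1 cells and across phases were set before.

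p53 target genes were lower within G1 cells with either inhibitor at 30 h, which the sums over all cells did not show. The list's median was -1.18 with the PI3K inhibitor and -0.64 with the MEK inhibitor in G1 cells (11 and 7 of 19 genes lower), against -0.14 and 0.19 over all cells, where it was not called (adjusted p = 0.34 and 0.87). Only 41 and 26 cells with EGF alone were called G1 at 30 h (18.4% and 8.0% of called cells in libraries 1 and 2). Both inhibitors were compared with these same cells, so the falls are not independent of each other. With the MEK inhibitor 64.2% and 33.2% of called cells were G1, and with the PI3K inhibitor 82.8% and 72.3%. A difference in which cells were called G1 cannot be told from an effect of the inhibitors, and the cause was not tested.

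Genes that had changed by 15 h of EGF may move back when MEK is inhibited. No cells without EGF were measured at 15 h, so an effect of EGF cannot be told from one of time in culture. The EGF response, and genes raised or lowered by EGF, here mean the change at 15 h against 0 h. Across genes, which are not independent replicates, the change at 15 h against 0 h and the change with the MEK inhibitor at 30 h, which share no sums, correlated with r = -0.573. Of 2105 genes called in both, 2030 (96.4%) went in opposite directions, among them CDKN1C, which fell by 2.96 with EGF, and DUSP4, which rose by 3.61. Within G1 cells r was -0.482 and 97.2% of 502 genes went in opposite directions, so the relation was also seen among cells called G1. At 30 h these were 41 and 26 cells with EGF alone and 204 and 189 with the MEK inhibitor in libraries 1 and 2. Whether they are alike in other ways was not tested, so a part of cell cycle phase in the relation is not excluded. For the PI3K inhibitor r was -0.270 over all cells, where 80.2% of 1733 genes went in opposite directions, but -0.019 within G1 cells, where 57.0% of 374 did. At 20 h it was -0.188 within G1 cells, where 83.2% of 376 genes went in opposite directions. Within G1 cells most genes called in both thus went against the EGF response with the PI3K inhibitor at 20 h. They were a part of that response: 188 of 1098 genes raised by EGF fell (32 rose), and 125 of 980 lowered by EGF rose (31 fell). At 30 h the r of -0.019 did not meet the value set beforehand for a reversal. The difference between the times was not tested. Library 2 enters the 15 h comparison with 29 and 64 cells, of which 11 and 19 were called G1.

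By list median, MEK/ERK output genes were lower with the MEK inhibitor in S and G2/M cells as in G1 cells. No test compared these sets of cells, and the members with enough counts can differ between them. The list's median at 30 h was -2.95 in S and G2/M cells and -2.52 in G1 cells, a ratio of 1.17, in line with an action of MEK on these genes outside G1 too. With the MEK inhibitor 13 and 16 of these cells were called S and 101 and 364 G2/M, so S phase was not examined by itself. This is a hypothesis; phases were called from transcripts of the same cells.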
